A study of Mus musculus with 3 samples.

How the data were processed

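The libraries held CD45+ cells sorted from the muscle layer of the stomach of female C57bl/6 mice, after digestion of the muscle with collagenase type II, per the labels' protocols. They were made with a droplet kit that reads the 3' end of transcripts and gives each captured molecule a unique molecular identifier (UMI), per the labels' protocols. The authors deposited UMI counts, not normalised, as 1 matrix of genes by cell barcodes per library, with 31053 Ensembl gene identifiers and 31017 different symbols. Counting was done with Cell Ranger 3.1 against the mouse build mm10, per the submitters' processing notes. Per the file headers the software version was 3.0.0 for replicate 1 and 3.1.0 for replicates 2 and 3, so the libraries were not all counted by 1 version. How reads that fit several genes were treated, and the annotation release, are not given in the sources used here. The lowest barcode totals were 504, 500 and 504 UMIs in replicates 1, 2 and 3, so barcodes had been selected on depth, while barcodes with a high mitochondrial share were still present.

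All 3 libraries belong to 1 group, named NonDiabetic in the labels. Diabetic samples were not analysed here. No pair of libraries was a copy: over 12670, 12621 and 12679 genes, the chi-square per degree of freedom was 106 for replicates 1 and 2, 80.7 for replicates 1 and 3, and 40.7 for replicates 2 and 3. A chi-square of about 1 would be expected from sampling noise alone.

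Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs. In replicates 1, 2 and 3, 349, 489 and 671 barcodes were over the mitochondrial limit, and 276, 390 and 623 were under the gene minimum. Doublets were scored with scrublet in scanpy, and the highest scores were removed at 0.8% of barcodes per 1000 barcodes of a library, which took 6, 64 and 32 barcodes. Counts were scaled to 10000 per cell and logged for clustering. Leiden clustering used 2000 highly variable genes per step, 30 principal components, 15 neighbours and a resolution of 1 for all cells and 0.5 within macrophage-like and dendritic cells. All 339 genes of the fixed lists were kept out of clustering. Over all steps, 4353 genes were used to cluster.

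Clusters were named from 26 fixed marker classes. A marker counted when found in at least 25% of a cluster's cells, and at least 3 such markers were needed. A cluster stayed unnamed when over 90% of its cells came from 1 library, or when its median UMI count was under 0.333 of its own library's with none of its markers among its 10 leading genes. Several choices were made after exploratory clusterings had been seen and before any differential test. These were the naming minimums, the 90% limit, the reference for low UMI counts, the merging of related classes, the removal of genes correlated over 0.2 with proliferation genes, and the centring of libraries before macrophage-like and dendritic cells were clustered again. Samples, tests, gene lists, markers, the rule for named genes and most alternatives were fixed before the data were examined.

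Shares of cells are given per library with exact Clopper-Pearson 95% intervals and as a mean with SD over the 3 libraries. A count of 0 allows up to 3 counts. Intervals and limits cover counting error only. To compare shares of cells with a UMI at equal depth, cells were thinned to 1000 UMIs and shallower cells were left out. Co-detection of a pair of genes was the log2 odds ratio per library with 0.5 added to each cell of the table, tested with an exact two-sided sign-flip test over libraries, whose smallest p is 0.25.

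For each of 3 comparisons between cell classes, raw counts were summed per library and class, giving 6 profiles, from at least 20 cells each and in at least 2 libraries. Sums were tested with the two-sided quasi-likelihood test of edgeR (glmQLFit and glmQLFTest) after filterByExpr and TMM scaling, with the library as a block and Benjamini-Hochberg adjustment over all genes tested. Calls were made at an adjusted p under 0.05. The block was part of the planned test, because each library gives both classes and the pairing follows from the design. Standard errors are the log2 fold change divided by the root of the F statistic. Classes were made from the same cells whose genes were then tested, so the p-values of genes that define or follow a class are too small. Counts of called genes therefore leave out clustering genes and markers, which removes only part of that double use.

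The 16 fixed lists, of 15 to 26 genes, were tested with camera from limma on log2 CPM with a prior count of 3, two-sided and adjusted over the 16 lists. The preset correlation between genes was 0.01, and each test was repeated with an estimated correlation. In the text, a list's adjusted p without further words is that with the preset correlation. A fold change is printed only where each class holds more than 3 counts. Where a class holds none, a lower bound is given against 3 counts over the whole class.

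Named genes follow 1 rule. From each fixed list it takes up to 2 members with the highest and up to 2 with the lowest fold change among those called with the same sign in every library, of which not all are printed. It adds the 5 highest and 5 lowest called genes with the same sign in every library and a mean of at least 100 CPM in 1 class that are neither clustering genes, markers, list members nor mitochondrial, ribosomal, antigen receptor or unnamed-model genes. It also takes 12 key genes whatever their values, among them Timd4, Lyve1, Folr2, Cd163, Mrc1, Ccr2, Cx3cr1, H2-Ab1, Hmox1, Bmp2 and Mki67. Results of some genes that the rule takes are not reported here. Any other gene printed with a value was chosen after its value was seen, which holds for all genes of the closing section outside these sets.

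The tests were checked on simulated counts in which 200 genes were changed, 50 at each size. All genes were drawn with a common dispersion and without library effects, and changed genes had a mean count of at least 20. Changes of 0.5, 1, 2 and 3 on the log2 scale were recovered for 2%, 64%, 100% and 94% of genes in the comparison with monocytes, for 6%, 84%, 96% and 98% in that with dendritic cells, and for 10%, 92%, 98% and 100% in that of macrophage subsets. False calls were 2 of 132, 6 of 148 and 6 of 156. Classes were set before the counts were drawn, so these rates do not cover the double use of cells for clustering and testing.

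Alternatives were a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), no cell filter, doublets kept, lower (0.5 and 0.3) and higher (2 and 1) resolution, 1000 clustering genes, thinning to 500 or 2000 UMIs, a gate on Timd4, Lyve1 or Folr2 UMIs, no library block, RLE size factors, no filter on low counts, DESeq2 (minimum total 10), profiles thinned to the lowest total, and each library left out in turn. Chosen after seeing the data were the runs without library centring, with all dendritic cells, without the CCR2-led cluster, without low-UMI macrophages, without barcodes shared by replicates 2 and 3, and shares over named cells. Gene positions were taken from GENCODE vM21 on GRCm38, the assembly behind mm10, by Ensembl identifier, and all 17 looked up were found. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.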

Results

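Single-cell RNA counts were made from CD45+ cells, CD45 being a surface protein of leukocytes, sorted from the stomach muscle of female C57bl/6 mice. The 3 libraries form 1 group, NonDiabetic, so no groups of animals were compared. They held 881, 2839 and 2015 barcodes with 6777422, 13336484 and 11017170 UMIs in replicates 1, 2 and 3. After filtering, 524, 2282 and 1299 cells remained, with medians of 9066.5, 1624 and 6696 UMIs. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The series asks which muscularis macrophages the stomach holds and from where they may derive. The comparisons take up the composition of the sorted cells, the subsets of macrophages, and how macrophages differed from monocytes, from conventional dendritic cells and among themselves.

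Macrophage-like cells were the most frequent named class in every library, and group 2 innate lymphoid cells (ILC2), which secrete type 2 cytokines, came next. Macrophage-like cells made up 42.9% ± 16.9 (SD, n = 3) of kept cells, with 40.3% in replicate 1, 27.5% in replicate 2 and 60.9% in replicate 3. Their exact 95% intervals were 36.0 to 44.6%, 25.7 to 29.4% and 58.2 to 63.6%, so the libraries differed by more than counting error. Of named cells alone, macrophage-like cells were 53.6% ± 12.2. ILC2-like cells, led by Arg1, Il7r, Klrg1 and Gata3 in one cluster and by Il5, Csf2, Il13 and Areg in another, were 13.9% ± 6.76. Dendritic cells, led by Cd209a, Ccl22, Ccl17 and Ccr7 or by Xcr1, Clec9a and Itgae, were 10.7% ± 4.60. Monocyte-like cells, led by Chil3, F10, Fn1 and Ifitm6, were 5.23% ± 2.70, and 3 of their 9 markers counted. T or NK cells were 2.19% ± 1.74 (1.19% without replicate 1), mast cells with Mcpt4, Cma1 and Cpa3 were 1.32% ± 0.194, B or plasma cells were 0.550% ± 0.587 (0.211% without replicate 2), and granulocytes with S100a8 and S100a9 came to 0.191%, 0.482% and 0.693% in the 3 libraries. Stromal-like cells with Dcn, Mgp and Col3a1, which a CD45+ gate should remove, were 3.57% ± 4.36, with 8.59% in replicate 1 and a mean of 1.06% without it. Unnamed cells made up 1.15%, 50.1% and 6.24% in replicates 1, 2 and 3, and 1068 of those of replicate 2 fell in 1 cluster of low UMI count. That cluster lowers the shares of named classes in replicate 2.

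**Figure D1:**
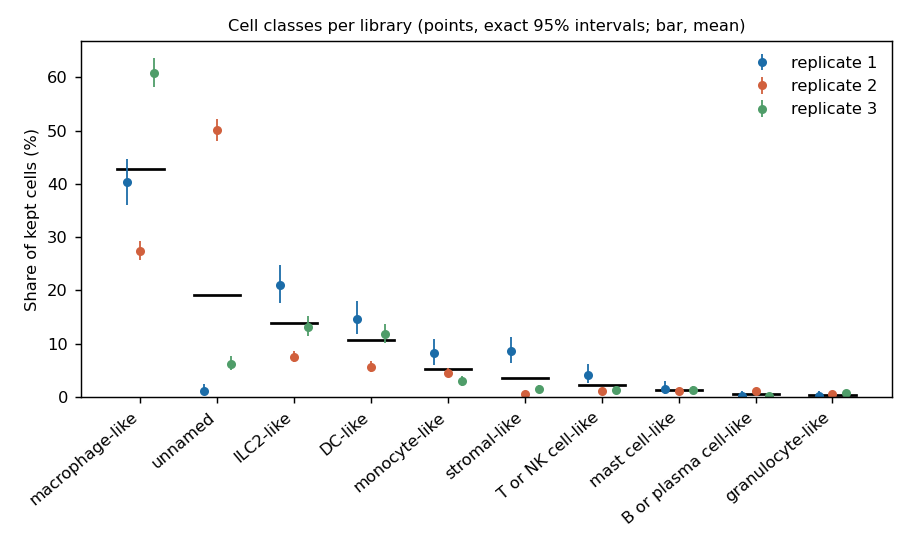
Share of kept cells (%, y axis) in 10 cell classes (x axis); points are the 3 NonDiabetic libraries with exact 95% intervals and bars are means over libraries. Macrophage-like cells lie at 40.3%, 27.5% and 60.9%, and unnamed cells reach 50.1% in replicate 2.

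Within macrophage-like cells, a subset with the Timd4, Lyve1 and Folr2 programme (TLF-like), known from self-maintained tissue macrophages, made up 29.2% to 37.2% of cells in each library. TLF-like cells were 34.1%, 37.2% and 29.2% of macrophage-like cells, a mean of 33.5% ± 4.02 (SD, n = 3). Their sub-clusters carried 12 of 12 subset markers; one was led by Lyve1, C4b, Cd209f and Vsig4, the other by Mt2, Ccl7, Hbegf and Ccl2, a metallothionein with growth factor and chemokine genes. Cells named CX3CR1-type were 51.2% ± 0.776 and those named CCR2-type, led by Lyz1, Fn1 and Ear2, 3.43% ± 1.06, with 11.9% ± 4.17 unnamed for low UMI counts. One CX3CR1-type sub-cluster was led by the inflammatory genes Il1a, Ptgs2 and Il1b. The border between CX3CR1-type and CCR2-type depended on the settings. With doublets kept the shares were 20.8% and 39.9%, and with the stricter cell filter 25.6% and 34.9%. Every other clustering that was run gave a lower CX3CR1-type and a higher CCR2-type share than the main one. The SDs over libraries do not cover this dependence. The mean TLF-like share ranged less, up to 41.7% with a gate on UMIs of Timd4, Lyve1 or Folr2. There 15.6%, 13% and 11.6% of cells lay next to the gate with 1 UMI. Single libraries moved more: the gate took 65 of 205, 291 of 593 and 322 of 726 thinned cells in replicates 1, 2 and 3. The lowest share then lay in replicate 1 instead of replicate 3.

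In 1524 of 1629 macrophage-like cells thinned to 1000 UMIs, Mrc1 and H2-Ab1 were the most detected key genes and Timd4 and Mki67 the least. The shares were read without sub-clusters, but the macrophage-like class itself came from clusters. The clustering genes over all steps included Timd4, Lyve1, Folr2, Cd163, Mrc1, Ccr2 and Cx3cr1. Mrc1, the mannose receptor, was found in 75.2% ± 3.89 of cells (unthinned 93.4%) against 2.38% of T or NK cells. H2-Ab1, a chain of MHC class II, was found in 65.5% ± 6.42 (83.6%) against 5.88%, and in 77.2% of B or plasma cells. Hmox1, the haem-degrading enzyme haem oxygenase 1, was found in 36.8% ± 4.10 (74.6%), Lyve1, a hyaluronan receptor, in 34.9% ± 7.95 (49.3%) and Cd163, a receptor for haemoglobin, in 33.9% ± 8.73 (54.1%). Folr2, a folate receptor, was found in 21.8% ± 8.59 (45.2%) against 1.33%, and Cx3cr1, the fractalkine receptor, in 19% ± 8.90 (41.0%). Bmp2, a growth factor that acts on enteric neurons, was found in 11.7% ± 1.82 (30.6%) against 6.85% of ILC2-like cells. Mki67, a gene of dividing cells, was found in 3.31% ± 0.812 (11.8%) against 1.52% of T or NK cells. Timd4, a receptor for phosphatidylserine, was found in 5.15% ± 1.04 (19.3%) and in 0 of 61 T or NK cells, which allows a share of up to 4.92%, and 0 of 440 ILC2-like cells, which allows 0.682%. Each of Lyve1, Cd163, Hmox1, Cx3cr1 and Bmp2 was likewise found in 0 of the 61 T or NK cells, and in ILC2-like cells Lyve1 was found in 0.210%, Cd163 in 0.195% and Hmox1 in 0.585%. Ccr2, the receptor that draws monocytes into tissue, was found in 21.2% ± 11.7 (37.8%), below the 32.7% of T or NK cells and 44.3% of ILC2-like cells, lymphoid cells in which the gene is also known, and its share ranged from 13.7% to 34.6% between libraries. Thinned cells had 1000 UMIs in every class; before thinning the medians of macrophage-like cells were 6977, 8794 and 7510 UMIs in the 3 libraries, and that of T or NK cells over all libraries was 6315. Timd4 lies on chromosome 11 (ENSMUSG00000055546, 46810800 to 46844332, plus strand), Lyve1 on chromosome 7 (ENSMUSG00000030787, 110850607 to 110863239, minus), Folr2 on chromosome 7 (ENSMUSG00000032725, 101839988 to 101857194, minus) and Ccr2 on chromosome 9 (ENSMUSG00000049103, 124101950 to 124113557, plus) of GRCm38. H2-Ab1 (ENSMUSG00000073421) spans 34257689 to 34269419 on the plus strand of chromosome 17, Hmox1 (ENSMUSG00000005413) 75093621 to 75100589 on the plus strand of chromosome 8 and Bmp2 (ENSMUSG00000027358) 133552159 to 133562885 on the plus strand of chromosome 2. All are annotated as protein-coding, and the counts are of whole genes.

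The genes of the TLF programme tended to be found in the same macrophages. Cells with them seldom held Ccr2 and held H2-Ab1 less often than other macrophages did. Many thinned cells held only part of the programme: 299 had Lyve1 without Folr2 and 504 had Lyve1 without Timd4. Of 83 thinned cells with Timd4, 68 also had Lyve1 and 47 had Folr2, with log2 odds ratios of 2.72 ± 0.99 and 2.37 ± 0.44 (SD, n = 3). Lyve1 and Folr2 were found together in 273 cells (2.69 ± 0.52). No thinned cell held UMIs of both Timd4 and Ccr2, which allows up to 0.197% of the 1524 cells and limits detection of both at this depth, not expression. The log2 odds ratio was -3.63 ± 0.49. The joint count of 0 enters it only as the added 0.5, so its size and spread depend on that constant. At 2000 UMIs 2 of 1404 cells held both, and with doublets kept or at lower resolution 1 did. Ccr2 was found with Lyve1 in 23 cells (-2.81 ± 0.32) and with Folr2 in 16 (-2.26 ± 0.77), but with H2-Ab1 in 237 of the 263 cells that had Ccr2 (2.60 ± 0.35). H2-Ab1 was also found less often in cells with Lyve1 (217 cells, -2.33 ± 0.65), with Folr2 (154 cells, -1.60 ± 0.33) and with Timd4 (26 of 83, -1.84 ± 1.33; -1.16 without replicate 2) than in those without. Each of the 10 pairs had the same sign in all 3 libraries, for which the exact two-sided sign-flip test gives p = 0.25, the smallest it can give with 3 libraries. At lower resolution Timd4 with H2-Ab1 kept its sign in 2 libraries only, from -2.54 to 0.02 (p = 0.5 by the same exact test).

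**Figure D2:**
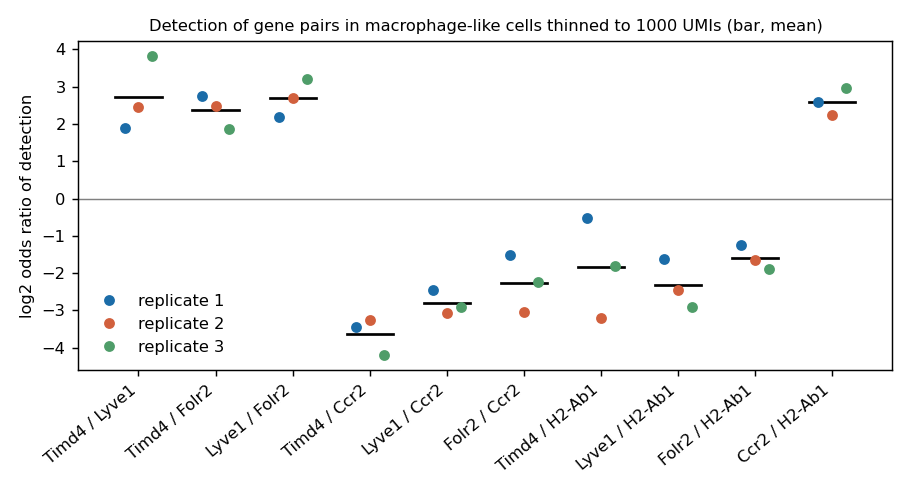
Log2 odds ratio of detection (y axis) for 10 pairs of genes (x axis) in macrophage-like cells thinned to 1000 UMIs; points are the 3 libraries and bars are means. Timd4 with Lyve1 (2.72) and Lyve1 with Folr2 (2.69) lie above 0, and Timd4 with Ccr2 (-3.63, with 0 cells holding both) lies below.

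Macrophage-like cells carried more RNA of trophic genes, the scavenger receptor Stab1 and the transcription factor Maf than monocyte-like cells of the same library, and less of glycolysis genes, MHC class II genes, Il6 and Il1b. Of the trophic list 11 of 17 genes were higher, and 10 of 17 glycolysis and 8 of 13 MHC class II genes were lower. These list calls rest on a preset correlation between genes; with an estimated one none of the 16 lists was called (adjusted p = 0.561 to 0.873). Stab1 stood at 515 against 20.5 CPM (log2 fold change 4.62 ± 0.21, SE, n = 3 libraries, adjusted p = 7.8e-08). Maf, a regulator of resident macrophages, stood at 1097 against 74.8 CPM (3.90 ± 0.17, adjusted p = 6.54e-08). The cytokine gene Il6 fell by 2.91 ± 0.33 on the log2 scale (42.5 against 295 CPM, adjusted p = 5.88e-05). Il1b was at 1015 ± 775 against 3747 ± 960 CPM (SD), a log2 fold change of -2.11 ± 0.20 (adjusted p = 1.5e-05). The comparison bears on whether monocytes are a source of these macrophages, and it describes only how the classes differ. Here and against dendritic cells, the macrophage-like class pools TLF-like and other cells, which differ in some of these genes. When these were compared, H2-Ab1 stood at 1082 CPM in TLF-like and 4969 CPM in other cells, and Il1b at 83.0 and 1499 CPM. Whether each subset alone differs from monocytes or dendritic cells was not tested. It used 211, 627 and 791 macrophage-like cells (1749937, 5605141 and 6002319 UMIs) and 43, 104 and 38 monocyte-like cells (565249, 1372636 and 309062 UMIs). Leaving aside clustering genes and markers, edgeR called 1183 of 5716 genes, 520 higher and 663 lower in macrophages. Smooth muscle markers, of cells that the gate should remove, were higher in macrophage-like cells too, Acta2 by 2.49 ± 0.41 and Tagln by 3.46 ± 0.43 on the log2 scale. The classes were made from the same cells, so in this and the following comparisons p-values rank genes between such classes and are not those of independent groups.

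Trophic genes rose as a group: 11 of 17 tested members were higher and 2 lower, the same numbers adjusted over the list alone (adjusted p = 0.00711; adjusted p = 0.656 with an estimated correlation). Bmp2 stood at 159 ± 22.2 against 13.9 ± 5.72 CPM (3.71 ± 0.30, adjusted p = 4.13e-06; 3.11 without replicate 2) and Pdgfc rose by 3.65 ± 0.43 (2.77 without replicate 2), while Vegfa fell by 1.89 ± 0.31. Of efferocytosis and scavenger genes 9 of 18 were higher and 1 lower, likewise over the list alone (adjusted p = 0.0377; adjusted p = 0.561 with an estimated correlation), and the lower one was the crosslinking enzyme Tgm2 (-1.47 ± 0.29). The call of the efferocytosis list was lost without replicate 1 (adjusted p = 0.128), without replicate 2 (0.0664), with doublets kept (0.260) and with no filter on low counts (0.146). Iron genes were higher for 6 of 15 and lower for 1, again the same adjusted over the list alone (adjusted p = 0.0293; adjusted p = 0.561 with an estimated correlation; 0.0533 without replicate 2 and 0.157 with doublets kept). The iron exporter Slc40a1, at 0 counts in monocytes, was at least 23.7-fold higher, and Hp, which encodes the haemoglobin-binding haptoglobin, was lower at 0.406 against 76.2 CPM (-6.91 ± 0.45, adjusted p = 7.93e-07).

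Glycolysis genes fell together: 10 of 17 were lower, and 11 adjusted over the list alone (adjusted p = 6.98e-05; adjusted p = 0.561 with an estimated correlation), among them the lactate transporter Slc16a3 (-3.07 ± 0.19) and phosphofructokinase Pfkp (-1.95 ± 0.17). Of MHC class II genes 8 of 13 were lower, also 8 adjusted over the list alone (adjusted p = 0.00334; adjusted p = 0.632 with an estimated correlation). They included H2-DMb2 (-2.70 ± 0.28), the co-stimulator Cd80 (-2.70 ± 0.18) and H2-Ab1, at 3723 ± 684 against 5925 ± 897 CPM (-0.68 ± 0.14, adjusted p = 0.00395), whose call was lost without replicate 2 (-0.43), without the library block and with doublets kept. Pro-inflammatory genes were lower for 7 of 15, and 8 adjusted over the list alone (adjusted p = 0.00592; adjusted p = 0.667 with an estimated correlation). The call was lost at higher resolution (adjusted p = 0.159) and with no cell filter (0.0750). Oxidative phosphorylation genes were lower for 6 of 23, also 6 over the list alone (adjusted p = 0.00856; adjusted p = 0.725 with an estimated correlation), and not without replicate 2 (adjusted p = 0.137) or in thinned profiles (0.0962). Oxidative stress genes were lower for 9 of 19 and higher for 2, or 9 and 3 adjusted over the list alone (adjusted p = 0.0260; adjusted p = 0.561 with an estimated correlation). That call was lost without replicate 3 (adjusted p = 0.0603), at higher resolution (0.0812), in thinned profiles (0.0580) and with no cell filter (0.0757). The cystine transporter Slc7a11 (-2.79 ± 0.28) and glutathione reductase Gsr (-1.55 ± 0.31) were lower, while Hmox1 was higher at 694.9 ± 171 against 375 ± 254 CPM (1.07 ± 0.28, adjusted p = 0.0148), a call lost without replicate 2 (0.58) and without the library block.

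The other 8 lists gave no call. Complement genes were higher for 7 of 13 and lower for 4 (7 and 5 adjusted over the list alone; list adjusted p = 0.294), with Vsig4, a complement receptor, at least 19.1-fold higher and C3 lower (-2.03 ± 0.21). Chemokines were higher for 6 of 17 and lower for 4 (6 and 5 adjusted over the list alone; 0.386), from Ccl12 (4.65 ± 0.24) to Ccl5 (-1.85 ± 0.18), and gave a call without replicate 3 (0.0472). Alternative activation genes were higher for 8 of 18 and lower for 4 (8 and 5 adjusted over the list alone; 0.294), with the receptor Tgfbr2 higher (2.81 ± 0.25) and Il1rn, the interleukin 1 antagonist, lower (-1.28 ± 0.22). The anti-inflammatory cytokine Il10 was higher (2.29 ± 0.51, adjusted p = 0.00624). It stood at 1.52 without replicate 2 and 3.32 without replicate 3, and DESeq2 did not call it. Lipid and lysosome genes were higher for 12 of 26 and lower for 2 (14 and 5 adjusted over the list alone; 0.0807), with the tetraspanin Cd63 higher (2.80 ± 0.22) and the lipase Lpl lower (-2.07 ± 0.15). That list gave a call without replicate 3 (0.0116) and without the library block (0.0365). Dissociation genes were higher for 7 of 25 (8 adjusted over the list alone; 0.0807), among them the immediate early gene Jun (2.73 ± 0.27), and gave a call without replicate 3 (0.00837). Interferon genes were higher for 2 of 21 and lower for 4 (3 and 5 adjusted over the list alone; 0.670), and their mean and median lay above 0 while the test pointed lower. Proliferation genes were higher for 1 of 22 and lower for 1 (1 and 1 adjusted over the list alone; 0.542), and Mki67 was not called (-0.20 ± 0.22, adjusted p = 0.561). Myeloid transcription factors were higher for 7 of 24 and lower for 8 (7 and 10 adjusted over the list alone; 0.443), with a mean above 0 and a median and test below; Bhlhe40 (-2.67 ± 0.20) and the nuclear receptor Nr4a2 (-2.25 ± 0.20) were lower.

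Outside the lists, Slco2b1, an organic anion transporter (ENSMUSG00000030737, chromosome 7, 99657804 to 99711340, minus strand), was higher, at 123 against 2.84 CPM (5.59 ± 0.34, adjusted p = 4.81e-07). Cd33 (2.57 ± 0.22) and Serinc3 (1.89 ± 0.16) were also higher. Agpat4, an acyltransferase of phospholipid synthesis (ENSMUSG00000023827, chromosome 17, 12118704 to 12219645, plus strand), was lower (-2.59 ± 0.21), and Csf2rb, a chain of the GM-CSF receptor, was lower too (-2.08 ± 0.18). The naming markers Lyve1 (4.32), Folr2 (4.62) and Cx3cr1 (2.22) were higher and Ccr2 lower (-1.03), the last not without the library block. Without the block 710 genes were called, 407 higher and 303 lower, DESeq2 called 680, thinned profiles 434 (249 higher, 185 lower), the run with doublets kept 671, and the run without replicate 2 678. One macrophage cluster was itself led by Lyz1, Lpl, Fn1 and Ccr2 with none of the macrophage markers among its leading genes, and without it 1319 genes were called.

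Against conventional dendritic cells, macrophage-like cells carried more RNA of the chemokine, trophic, iron handling, and lipid and lysosome lists, and less of MHC class II genes. In these lists 15 of 17, 14 of 16, 14 of 14 and 17 of 25 genes were higher and 11 of 14 lower, but no list was called with an estimated correlation (adjusted p = 0.175 to 0.636). Pf4, a chemokine also stored in platelets, stood at 2036 against 10.4 CPM (log2 fold change 7.65 ± 0.23, SE, n = 3 libraries, adjusted p = 5.48e-09). Igf1, a growth factor, stood at 245 against 1.66 CPM (7.19 ± 0.29, adjusted p = 1.64e-08), the latter from 5 UMIs. H2-Ab1 was lower, at 3651 ± 714 against 10538 ± 493 CPM (SD; -1.55 ± 0.14, adjusted p = 4.83e-06). H2-Oa, whose product with that of H2-Ob dampens peptide loading of class II, was far lower at 1.30 against 87.2 CPM (-6.22 ± 0.27, adjusted p = 2.19e-08). Dendritic cells here are the cDC1-like and cDC2-like cells, 52, 70 and 106 per library with 962884, 1058843 and 1270931 UMIs; 1 of 2 cDC2-like sub-clusters was led by stress and cycle genes (Hspb1, Jun, Cenpf) and the other by Ifit1, Isg15, Ccl5 and Ccl22. Leaving aside clustering genes and markers, edgeR called 2100 of 5692 genes, 1012 higher and 1088 lower in macrophages. Acta2 (2.64 ± 0.34) and Tagln, which passed the test as well, were again higher in macrophage-like cells.

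Chemokines rose as a group: 15 of 17 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 3.61e-07; adjusted p = 0.175 with an estimated correlation). Ccl12, which attracts monocytes, was higher by 6.95 ± 0.28, and the lower one, Ccl5 (-1.96 ± 0.29; -1.35 without replicate 2), turned positive in 5 other settings, up to 3.88 with doublets kept. Trophic genes were higher for 14 of 16, also over the list alone (adjusted p = 1.07e-06; adjusted p = 0.175 with an estimated correlation), with Bmp2 at 155 against 1.81 CPM (6.28 ± 0.34; 7.08 without replicate 3). Iron genes were higher for 14 of 14, also over the list alone (adjusted p = 1.71e-06; adjusted p = 0.175 with an estimated correlation), and Slc40a1, at 0 counts in dendritic cells, was at least 34.7-fold higher. Lipid and lysosome genes were higher for 17 of 25 and lower for 1, or 18 and 1 adjusted over the list alone (adjusted p = 1.23e-06; adjusted p = 0.217 with an estimated correlation), with the cholesterol exporter Abca1 at 249.8 against 4.66 CPM (5.74 ± 0.26) and the tetraspanin Cd9 lower (-1.93 ± 0.27). Efferocytosis genes were higher for 11 of 18 and lower for 1, or 12 and 2 adjusted over the list alone (adjusted p = 0.000136; adjusted p = 0.217 with an estimated correlation). Mertk, a receptor for dying cells, had 0 counts in dendritic cells and was at least 87.3-fold higher. Complement genes were higher for 8 of 13 and lower for 1, or 11 and 2 adjusted over the list alone (adjusted p = 0.000707; adjusted p = 0.251 with an estimated correlation), the lower one being the integrin Itgax (-1.83 ± 0.18). Alternative activation genes were higher for 10 of 17 and lower for 3, likewise over the list alone (adjusted p = 0.00515; adjusted p = 0.309 with an estimated correlation), with Retnla at 3896 against 103 CPM (5.26 ± 0.21) and Il10, an anti-inflammatory cytokine, at 496 against 8.01 CPM (5.97 ± 0.29; 6.57 without replicate 2).

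MHC class II genes were lower for 11 of 14 and higher for 1, the same adjusted over the list alone (adjusted p = 3.13e-06; adjusted p = 0.365 with an estimated correlation), H2-Ob among them (-3.99 ± 0.18). Glycolysis genes were lower for 12 of 17 and higher for 1, also over the list alone (adjusted p = 0.00145; adjusted p = 0.360 with an estimated correlation), with the glucose transporter Slc2a3 (-2.50 ± 0.23) and Pfkp (-2.12 ± 0.18) lower. Oxidative phosphorylation genes were lower for 12 of 23, or 13 adjusted over the list alone (adjusted p = 0.00255; adjusted p = 0.270 with an estimated correlation), cytochrome c (Cycs, -1.41 ± 0.14) the most. Proliferation genes were lower for 8 of 23, or 7 adjusted over the list alone (adjusted p = 0.00515; adjusted p = 0.536 with an estimated correlation), with Mki67 at -0.88 ± 0.17 (adjusted p = 0.0018). The call of the proliferation list was lost without replicate 1 (adjusted p = 0.0575) and without the barcodes shared by replicates 2 and 3 (0.231).

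The other 5 lists gave no call. Oxidative stress genes were higher for 6 of 19 and lower for 3 (the same adjusted over the list alone; list adjusted p = 0.482), with Hmox1 at 679 ± 159 against 108 ± 68.6 CPM (2.77 ± 0.25, adjusted p = 6.06e-06) and Prdx6, a peroxiredoxin, lower (-1.42 ± 0.17). Pro-inflammatory genes were higher for 6 of 15 and lower for 3 (7 and 4 adjusted over the list alone; 0.269), with Tnf higher (1.64 ± 0.29) and Il1b lower (-1.31 ± 0.24), the latter above 0 in 4 other settings (up to 1.00 with doublets kept). Dissociation genes were higher for 11 of 25 and lower for 5 (12 and 6 adjusted over the list alone; 0.251), from Egr1 (1.99 ± 0.22) to Dnajb1 (-1.04 ± 0.19). Interferon genes were higher for 7 of 21 and lower for 3 (the same adjusted over the list alone; 0.157), with the antiviral gene Rsad2 higher (3.79 ± 0.31; 3.19 without replicate 1 and 4.52 without replicate 2) and Ifi205, of a family with near-identical members and so uncertain, lower (-4.94 ± 0.28). Myeloid transcription factors were higher for 13 of 24 and lower for 9 (the same adjusted over the list alone; 0.251), with Maf (6.97 ± 0.29) higher and Bhlhe40 lower (-3.18 ± 0.16).

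Outside the lists, Slco2b1 (6.49 ± 0.35; 7.65 without replicate 3), Rhoc (3.38 ± 0.22) and Lst1 (3.21 ± 0.18) were higher. Kitl, the ligand of the receptor Kit, stood at 119.5 against 12.6 CPM (3.18 ± 0.43, adjusted p = 0.000119; 4.42 without replicate 1 and 2.57 without replicate 2). Agpat4 (-2.67 ± 0.17) and Rnase6 (-2.54 ± 0.27) were lower. Ccr2 (-0.14 ± 0.19, adjusted p = 0.612) and Timd4 (-0.24 ± 0.27, adjusted p = 0.519) were not called, though Ccr2 was called lower without replicate 1 (-0.46) and Timd4 without replicate 3 (-0.76). Without the library block 1306 genes were called, 733 higher and 573 lower.

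Among macrophages, TLF-like cells carried less RNA of MHC class II genes, proliferation genes and Il1b than other macrophage-like cells of the same library, and more of complement and iron handling genes. Of these lists 10 of 13 and 19 of 22 genes were lower and 8 of 13 and 9 of 15 higher. No list was called with an estimated correlation (adjusted p = 0.443 to 0.923), and the iron list not in thinned profiles (0.104). Vsig4 stood at 67.6 against 2.60 CPM (log2 fold change 4.67 ± 0.24, SE, n = 3 libraries, adjusted p = 9.19e-12). Tfrc, the transferrin receptor, stood at 299 against 37.7 CPM (2.92 ± 0.15, adjusted p = 9.66e-12). H2-Ab1 was lower at 1082 ± 456 against 4969 ± 646 CPM (SD; -2.28 ± 0.20, adjusted p = 2.69e-08). Mki67 was lower at 22.5 ± 11.2 against 97.2 ± 24 CPM (-2.47 ± 0.23, adjusted p = 4.99e-08), and Il1b at 83.0 ± 86.3 against 1499 ± 1250 CPM (-4.36 ± 0.20, adjusted p = 3.48e-12). The comparison asks how macrophages with the programme of long-lived residents differ from the rest. It used 72, 233 and 231 TLF-like cells (345394, 1874786 and 1735236 UMIs) and 139, 394 and 560 others (1404543, 3730355 and 4267083 UMIs). Leaving aside clustering genes and markers, edgeR called 1947 of 6013 genes, 918 higher and 1029 lower in TLF-like cells. Markers of other tissue moved with the subset. All 7 tested smooth muscle markers were called higher in TLF-like cells, Actg2 and Cnn1 without being so in replicate 1. All 5 tested markers of stomach epithelium were called higher as well. Acta2 stood at 46.9 ± 9.27 against 18 ± 8.47 CPM (1.27 ± 0.20) and Tff1, a mucus peptide gene, at 38.9 ± 26.2 against 7.34 ± 5.72 CPM (2.41 ± 0.23). TLF-like cells were also shallower, with medians of 4458, 7603 and 7159 UMIs against 9800, 9385.5 and 7716.

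MHC class II genes fell together: 10 of 13 were lower and 1 higher, or 11 and 1 adjusted over the list alone (adjusted p = 2.04e-05; adjusted p = 0.443 with an estimated correlation), H2-Eb1 at 900.5 against 5553 CPM (-2.68 ± 0.21). Proliferation genes were lower for 19 of 22, also over the list alone (adjusted p = 0.000162; adjusted p = 0.570 with an estimated correlation), the replication factor Pclaf the most (1.85 against 42.1 CPM). Oxidative phosphorylation genes were lower for 13 of 23 and higher for 1, also over the list alone (adjusted p = 0.00979; adjusted p = 0.443 with an estimated correlation), Cox5b (-0.96 ± 0.16) and Sdhb (-0.80 ± 0.16) among them. Glycolysis genes were lower for 10 of 17 and higher for 1, or 11 and 1 adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.443 with an estimated correlation). Their call was lost without replicate 3 (adjusted p = 0.0624) and in thinned profiles (0.0693). The glucose transporter Slc2a1 (-2.55 ± 0.30) and Gapdh (-1.63 ± 0.19) were lower. Iron genes were higher for 9 of 15 and lower for 2, or 10 and 2 adjusted over the list alone (adjusted p = 0.00377; adjusted p = 0.443 with an estimated correlation; 0.104 in thinned profiles). The lower ones were the ferritin chains Fth1 (-0.57 ± 0.15) and Ftl1 (-0.46 ± 0.15), which store iron, and both calls were lost without replicate 2 and without replicate 3. Complement genes were higher for 8 of 13 and lower for 1, also over the list alone (adjusted p = 0.0110; adjusted p = 0.443 with an estimated correlation). C4b was higher (3.78 ± 0.18), which is uncertain because its copy C4a is nearly identical, and Itgax was the lower one (-4.49 ± 0.36).

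**Figure D3:**
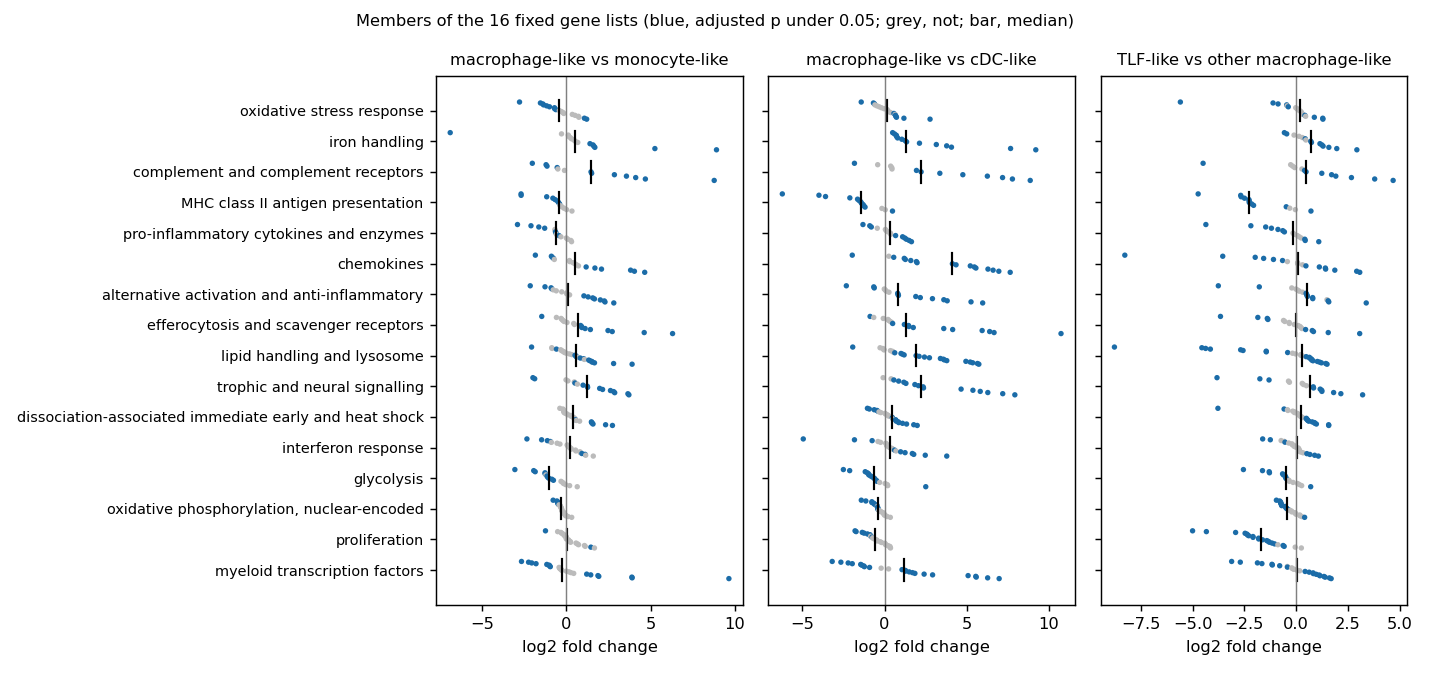
Log2 fold change (x axis) of the tested members of 16 gene lists (y axis) in the 3 comparisons; points are genes, blue at an adjusted p under 0.05 and grey otherwise, and bars are list medians. All 14 iron genes lie above 0 against dendritic cells, and 19 of 22 proliferation genes are called lower in TLF-like cells.

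The other 10 lists gave no call. Alternative activation genes were higher for 9 of 17 and lower for 2 (10 and 2 adjusted over the list alone; list adjusted p = 0.0742), with the lectin Clec10a at 811.5 against 76.1 CPM (3.38 ± 0.18), Retnla at 7612 against 2690 CPM (1.57 ± 0.19) and Il1rn lower (-3.76 ± 0.21). Dissociation genes were higher for 11 of 25 and lower for 2 (11 and 4 adjusted over the list alone; 0.0742), with Klf2 higher (1.57 ± 0.14) and Rgs1 lower (-3.78 ± 0.20). Trophic genes were higher for 8 of 16 and lower for 3 (9 and 3 adjusted over the list alone; 0.0996), with Pdgfc (3.20 ± 0.18) and Hbegf (2.15 ± 0.16) higher and Pdgfb (-1.75 ± 0.21) lower. Bmp2 was higher at 285 ± 101 against 121 ± 38.6 CPM (1.23 ± 0.23, adjusted p = 0.000347), between 0.69 and 1.70 with 1 library left out. Pro-inflammatory genes were higher for 3 of 15 and lower for 7 (the same adjusted over the list alone; 0.122). Chemokines were higher for 7 of 17 and lower for 6 (the same adjusted over the list alone; 0.769), with a mean below 0 and a median and test above. Ccl8 (3.06 ± 0.18) and Ccl24, which attracts eosinophils (2.92 ± 0.15, 418 ± 6.72 against 55.5 ± 2.53 CPM), were higher and Ccl5 lower (-3.54 ± 0.32; -4.85 without replicate 2 and -2.72 without replicate 3).

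Lipid and lysosome genes were higher for 12 of 26 and lower for 9 (the same adjusted over the list alone; 0.869), with progranulin (Grn, 1.49 ± 0.15) higher, osteopontin (Spp1, -4.55 ± 0.30) lower and Gpnmb, at 0 counts in TLF-like cells, at least 33.7-fold lower. Oxidative stress genes were higher for 4 of 19 and lower for 5 (5 and 6 adjusted over the list alone; 0.869), with Hmox1 at 1246 ± 198 against 513 ± 88.5 CPM (1.28 ± 0.15, adjusted p = 8.99e-07) and thioredoxin (Txn1, -1.12 ± 0.16) lower. Interferon genes were higher for 4 of 22 and lower for 3 (the same adjusted over the list alone; 0.869). In the lipid, oxidative stress and interferon lists the mean lay below 0 and the median and test above. Efferocytosis genes were higher for 5 of 18 and lower for 4 (5 and 5 adjusted over the list alone; 0.869), with a mean below 0 and a median near 0; the receptor Axl was lower (-1.85 ± 0.15) and Colec12 higher (3.06 ± 0.19). Myeloid transcription factors were higher for 11 of 25 and lower for 8 (the same adjusted over the list alone; 0.922), with a mean below 0 and a median and test above, Irf4 (1.68 ± 0.17) and Spic (1.60 ± 0.23), known from iron-recycling macrophages, higher, and Runx3 (-3.11 ± 0.24) lower.

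Outside the lists, Rcn3 (ENSMUSG00000019539, chromosome 7, 45082913 to 45092221, minus strand; 2.99 ± 0.17) and Tcn2, a carrier of vitamin B12 (1.82 ± 0.15), were higher, and the lectin Clec4b1 (ENSMUSG00000030147, chromosome 6, 123049962 to 123071555, plus strand; -3.06 ± 0.22, and -3.75 without replicate 2), the actin regulator Coro1a (-1.90 ± 0.16) and the adhesion molecule Alcam (-1.88 ± 0.18) were lower. The naming markers Timd4 (3.66), Lyve1 (3.48), Folr2 (2.66), Cd163 (1.91) and Mrc1 (1.25) were higher, and Ccr2 (-2.66) and Cx3cr1 (-3.68) lower. These define the classes. Some naming markers went against their class: Fcrls of the TLF set was lower (-0.78), and Siglech (1.83) and P2ry12 (1.10) of the CX3CR1 set were higher. Without the library block 576 genes were called, 280 higher and 296 lower, and DESeq2 called 967, thinned profiles 783, the run without replicate 2 1118 and that without replicate 3 934.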

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

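The tests of the low-UMI cluster, of heat shock genes and of other splits of the profiles were chosen only after the results were seen, while the test of RNA shared between libraries was written before its result was measured.

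Among barcodes left out because over 15% of their UMIs were mitochondrial, smooth muscle markers appeared above the limit that a count of 0 allows, which macrophage-like cells of replicates 2 and 3 also pass. At least 3 of 8 such markers were found in 4.87% of 349 barcodes in replicate 1, 17.2% of 489 in replicate 2 and 24.4% of 671 in replicate 3, where counts of 0 would allow 0.860%, 0.613% and 0.447%. In macrophage-like cells of the same libraries the shares were lower, 0.474%, 11.8% and 11.5%, at higher median depths (6977, 8794 and 7510 against 2092, 1465 and 1322 UMIs), and the exact 95% intervals lay apart in replicates 1 and 3. Acta2, the actin of smooth muscle, stood at 51.6, 476 and 973 CPM in these barcodes and at 16, 25.2 and 34.7 CPM in macrophage-like cells.

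A cluster of 1070 kept cells, 1068 of them from replicate 2, held 46.8% of that library's kept cells at a median of 979 UMIs and entered no comparison; no biological explanation was tested, since the design gives 1 group. Shallow cells of several types are argued against: with barcodes thinned to 900 UMIs, 62.5% (59.0 to 66.0%, 469 of 750) held both a macrophage and an ILC2 marker, against 9.31% (7.32 to 11.6%) of named macrophage-like and ILC2-like cells, or 7.83% with macrophage-like cells of low UMI count included. Damaged macrophages as the whole cluster are argued against by these ILC2 markers. Malat1, a nuclear RNA, stood at 0.325 times its level in 573 macrophage-like cells of that library (0.308 to 0.343). The ratio was 0.327 with the library's 54 macrophage-like cells of low UMI count added and 0.477 (0.297 to 0.854) against these alone. Low Malat1 argues only against damage that loses cytoplasm and keeps the nucleus. It cannot test damage that loses the nucleus. The median mitochondrial share was 7.02% against 3.07%, which damage would also raise. Free RNA in empty droplets stays a candidate explanation: relative to named cells, the median log2 ratio of ILC2 markers exceeded that of macrophage markers by only 0.31 (95% interval -0.08 to 0.65), as a mixture of the whole suspension needs. Against a plain mixture of the named cells alone, Clps stood at 213 against 11.3 CPM, Ccl2 at 5782 against 2193 and Cxcl1 at 3008 against 1024.

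Heat shock genes had their highest mean in replicate 3 in 5 of 6 classes and in replicate 2 in stromal-like cells, and no biological explanation was tested. Classes differed too: within replicate 3 the mean log2 CPM ran from 9.44 in stromal-like to 11.86 in dendritic cells, while libraries differed by 0.31 to 1.42 within a class. Free RNA is argued against as the whole cause, because Hspa1a in ILC2-like cells of replicate 3 stood at 6548 CPM, 61.2 times the 107 CPM that their 1.36% of foreign RNA allows. Handling of the whole suspension stays open, since 1 library per handling cannot be told apart from the mice it came from and 1 of the 6 classes went another way. That class, the stromal-like cells, held only 45, 15 and 19 cells in replicates 1, 2 and 3. T or NK cells, highest in replicate 3, held only 22, 26 and 16. Immediate early genes were highest in replicate 1 in 6 of 6 classes, and chemokines in replicate 2 in 5 of 6.

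Replicates 2 and 3 shared 33 barcodes, against 0 and 1 in the other pairs, and no biological explanation was tested. The profiles of a shared barcode correlated across genes at a mean r of 0.139, against 0.003 for the same profiles paired at random (central 95% -0.029 to 0.037; permutation p = 1e-05, the smallest that 100000 resamples can give). In 33 of 33 pairs r lay above the random mean, and the median UMI ratio of the deeper to the shallower profile was 49.5. Exchange of molecules between these libraries may explain the shared barcodes; where it happened stays open. Without these barcodes 1164, 2036 and 1886 genes were called against monocytes, against dendritic cells and among macrophages.

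In each comparison the 6 profiles can be split in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10 each time, gave its 1183, 2100 and 1947 called genes. The highest of the other splits gave 0 in each comparison by edgeR, with 183, 56 and 359 genes at an unadjusted p under 0.05 against 1904, 2596 and 2514 in the real split. Of the 4 splits that part the classes in all 3 libraries, the other 3 gave at most 30, 15 and 100 genes at that p. Every split but the real one mixes profiles of both classes within a group, and the classes were clustered to differ. The outcome was thus largely set in advance, and no conclusion is drawn from it.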

How the results depend on the processing

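The runs without library centring, with all dendritic cells, without the CCR2-led cluster, without low-UMI macrophages, without shared barcodes and over named cells were chosen only after the data were seen, as were the single values followed here for shares. Of these lead results, 129 alternatives gave the same outcome, 25 shares moved by more than the spread between libraries and 15 counts of genes or lists fell beyond 1.5 times; the cause was not tested except where stated. Over all other genes, lists, shares and pairs, 4732 alternatives gave the same outcome, 174 lost a call, 45 gained one, 23 moved and 13 reversed; of these, 3689 and the 13 reversed concern named genes.

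With no cell filter, the macrophage-like share was 24.7%, TLF-like 39.2%, CX3CR1-type 31.9%, CCR2-type 28.9% and the Timd4 share 7.25%. With doublets kept, TLF-like was 39.3%, CX3CR1-type 20.8%, CCR2-type 39.9% and the Timd4 share 6.41%. At higher resolution these were 39.6%, 31.5%, 28.9% and 6.65%, and at lower resolution CX3CR1-type was 43.1%, CCR2-type 19.5% and the Timd4 share 6.26%. The stricter filter gave CX3CR1-type 25.6% and CCR2-type 34.9%, 1000 clustering genes 38.7% and 31.2%, and no library centring 43.5% and 11.3%. The gate gave TLF-like 41.7%. Thinning to 500 or 2000 UMIs gave Timd4 shares of 3.81% and 10.1%, as fewer or more UMIs per cell must.

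Against monocytes, 671 genes were called with doublets kept (2 libraries left), 710 without the replicate block, 680 with DESeq2 and 434 in thinned profiles, which hold fewer UMIs and tested genes; with 1 library left out, 678 to 1185. Against dendritic cells, 1306 were called without the block. Among macrophages, 576 were called without the block, 967 with DESeq2, 783 in thinned profiles and 934 to 2411 with 1 library left out. The block is the pairing of both classes within a library; without it 68.5% of the 2081 genes called against monocytes, 68.3% of 3399 against dendritic cells and 35.3% of 3028 among macrophages, clustering genes and markers included, kept their call, with no change of sign. Leaving out the block changed 1 list call, lipid genes against monocytes, and no other of 48. Other settings ended list calls too: 4 in thinned profiles, 2 each with doublets kept, at higher resolution and with no cell filter, 1 with no filter on low counts and 1 without shared barcodes. They also added calls, 6 with doublets kept, 5 with no cell filter, 4 in thinned profiles and 4 at lower resolution. Dissociation genes were among these against monocytes and among macrophages. With an estimated correlation 0 lists were called in each comparison by camera, where adjusted p ranged from 0.561 to 0.873, 0.175 to 0.636 and 0.443 to 0.923. Lists called against monocytes numbered 5 to 10 with 1 library left out, 5 without replicate 2.

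Among the named genes, the log2 fold changes of 4 called genes changed sign. Ube2c against monocytes, reported at -1.25, was 3.70 with doublets kept and 0.15 with no cell filter. Against dendritic cells, Ptger4 (-0.65) was 0.22 and 0.24 under these settings, Ccl5 (-1.96) 3.88 and 3.87, and Il1b (-1.31) 1.00 and 0.91. Ccl5 was also 1.34 with 1000 clustering genes, 1.51 at lower resolution and 1.39 without centring, and Il1b 0.28 at lower resolution and 0.13 without centring. Of all genes called, clustering genes and markers included, more had the opposite sign. Against dendritic cells these were 9 with doublets kept, 6 with no cell filter, 2 at lower resolution and 1 with 1000 clustering genes. Against monocytes 5 had it with doublets kept, and among macrophages 1 with the gate. With no filter on low counts the median log2 fold change of all genes moved to 0.39, 0.27 and -0.11 in the 3 comparisons, and with DESeq2 to 0.17 against monocytes, so fold changes there are relative to that shift. No value against monocytes could be had with the stricter filter, where 14, 46 and 15 monocyte-like cells were named in replicates 1, 2 and 3. Nor could any be had at lower resolution or with 1000 clustering genes. There 0 monocyte-like cells were named in every library, so the class did not form. The shallowest profile against monocytes held 309062 UMIs, from replicate 3, and it is to this depth that profiles were thinned there.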

Other observations

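No tests were run in this part, and its genes other than Timd4, Kitl and Retnla were chosen only after their values were seen. In ILC2-like cells thinned to 1000 UMIs, Areg, a growth factor for epithelium, was found in 33.6% ± 10.3 (SD, n = 3 libraries), Csf2, which encodes GM-CSF, in 29.1% ± 9.34 and Arg1, an arginase, in 25.5% ± 8.01. In macrophage-like cells at the same depth, Areg was found in 4.39%, 9.78% and 3.03% in replicates 1, 2 and 3 and Arg1 in 4.88%, 1.01% and 0.138%. Csf2 was found there in 3 of 593 cells of replicate 2 and in 0 of 205 and 0 of 726 cells of the others (exact 95% upper bounds 1.78% and 0.507%). Il4 was found in 10.3% ± 1.75 of ILC2-like cells and in 48.1% ± 23.5 of mast cells, and in 2 macrophage-like cells, both of replicate 3. The ILC2 markers Il5 and Il13, which named the class, were found in 18.9% ± 5.39 and 18.2% ± 4.58, and Il13 in 0 of 8, 5 of 21 and 4 of 16 mast cells of the 3 libraries, too few to order the classes.

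Timd4 was not limited to macrophages. In cDC1-like cells, summed in 2 libraries, it stood at 96.0 ± 65.9 CPM and was found in 29.0% ± 12 of cells, unthinned, against 165 ± 41.0 CPM and 46.0% ± 10.6 in TLF-like macrophages, 12.9 ± 3.68 CPM in CX3CR1-type cells, with 1 UMI in all ILC2-like cells. Kitl, which maintains Kit-bearing interstitial cells of Cajal and mast cells, stood at 185 ± 42.8 CPM in TLF-like macrophages and 136 ± 65.1 in stromal-like cells, which lay within the spread of each other, at 49.9 ± 28 in monocyte-like cells, with 3, 1 and 1 UMIs in ILC2-like cells of the 3 libraries. Retnla stood at 7662 ± 62.6 CPM in TLF-like macrophages and 7089 ± 1684 in monocyte-like cells, but at 3243, 871 and 813 in CX3CR1-type cells of replicates 1, 2 and 3. With the TMM scaling of the comparison among macrophages, Retnla stood at 7612 ± 558 CPM in TLF-like cells, a wider spread between libraries.

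Gast, the gene of the stomach hormone gastrin (ENSMUSG00000017165, chromosome 11, 100334407 to 100336996, plus strand), led a macrophage cluster, yet 4169 of its 4231 UMIs came from 1 cell of 5054 UMIs in replicate 3, and 43 cells held any.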
